A study of Mus musculus with 15 samples.

How the data were processed

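RNA from sorted aortic macrophages (F4/80+ CD64+) of Apoe-/- mice on a high fat diet for 4 weeks was sequenced after low-input Smart-Seq2 amplification, in which cDNA from a small number of cells is amplified by PCR before the library is made. Per the labels' protocols, each sort held between 100 and 200 cells, the cDNA was amplified for 18 cycles and the tagmented library for 9 more, and the sorts were technical replicates taken from the pooled aortas of 4 female mice. Libraries were labelled Olfr2+ or Olfr2- according to the sort. Nothing in the labels says that the numbered samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

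The deposited values were whole-number counts of reads per gene, not normalized, for 47729 annotated features in 15 columns. The submitters' processing notes name STAR 2.7.1, DRAGEN and DESeq2 1.34 and the build GRCm39, without saying which step each served. The strand setting and the annotation release are not given in the sources used here. 98.9% of the gene identifiers, compared without their version, were also in the GENCODE annotation supplied for this work, which is of the older build GRCm38. Gene symbols were used as the deposited table gives them (Sepp1 is now Selenop and Olfr2 is now Or6a2), and no coordinates are given because the build behind the table could not be settled. Where a symbol named more than 1 feature, which happened for 126 symbols, the feature with the most counts was used for the gene lists. All rows named a gene. Counts of antisense and overlapping genes, and of paralogs such as the olfactory receptor genes, are uncertain because reads from them may not be told apart. Smart-Seq2 does not mark the strand and carries no molecular identifiers, so counts are not independent molecules.

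The number in each title (1, 3 and 4 for Olfr2-, 2, 3 and 4 for Olfr2+) was read as a sorted sample and the letter as a repeat, which gives the 3 per group that the labels name but is not stated there, and the 15 columns carry 8 library names. The values do not settle this reading: within a depth set, columns that share a library name had a median correlation of 0.671 and columns of other numbered samples of the group 0.666. Counts were summed over the columns of each numbered sample, giving 3 samples against 3. A chi-square comparison of counts over genes gave at least 688 per degree of freedom for each of the pairs of columns, those that share a library name included, so no pair agreed within sampling noise and none was counted as 1 library deposited more than once. Column totals ran from 29.9 to 95.6 M counts (M, 1000000). They left a gap between 53.2 and 76.0 M, and 60 M was used to divide the columns into 7 above and 8 below. This division was chosen after seeing the data.

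Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, edgeR's expression filter by group and a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was taken from its F statistic. Levels are CPM (counts per 1000000) scaled with the TMM factors where a mean ± SD is given, and CPM of the column total elsewhere. 25 gene lists were fixed before the data were examined and were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted over the lists. They cover macrophage states, pathways, RNA quality, and markers of other cells that an aortic sort could hold. Camera with an estimated correlation and fry were alternatives. DESeq2 1.42.0, limma-voom, other scalings and filters, other units of replication, the sample number as a block, and the omission of each sample were alternatives chosen before the data were examined. The comparisons within or adjusted for the depth sets, the list tests on library totals, and the 2 settings that part the 10 CPM filter from its scaling, were added after seeing the data.

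The genes named are Olfr2, the 12 with the largest log2 fold change in each direction among those that passed without overlap between the groups and with a mean of at least 10 CPM, list members that passed, and up to 4 members of each list as examples. Gene models without a proper symbol were counted and not named. No lower gene met the level and symbol requirements for the 12 largest. Had fewer than 5 genes passed in a direction, those with the smallest unadjusted p would have been given as values.

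The fits were tested on simulated data, with larger changes set after a first run recovered few. With counts drawn for the 24362 genes of the main comparison and 200 of them changed, 0 of 50 genes changed by 1 on the log2 scale were recovered, 2 of 50 changed by 3, 20 of 50 changed by 5 and 45 of 50 changed by 7, with 1 of 24162 unchanged genes called. The changed genes were drawn among those averaging above 10 CPM, so these rates do not cover genes at lower levels. The corresponding numbers for the comparison of columns below 60 M counts, over 29989 genes, were 0, 0, 4 and 17 of 50, with 0 of 29789 unchanged genes called. A list shifted by 2 on the log2 scale in the main comparison was called with a camera adjusted p of 1.86e-08, and 0 of 24 other lists were. Genes were drawn independently of each other there, so this does not test list calls among genes that vary together. In the real data the estimated correlation was 0.912 for the fibroblast list. 3 samples against 3 allow an exact permutation p no smaller than 0.1, so no such test is given for single values.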

Results

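Gene expression was measured in macrophages sorted from the atherosclerosis-prone aorta of Apoe-/- mice, which lack apolipoprotein E, with the question of how cells that carry the olfactory receptor Olfr2 differ from those that do not. The libraries labelled Olfr2- comprised 3 numbered samples in 5 columns, and those labelled Olfr2+ comprised 3 numbered samples in 10 columns. Summed per sample, the totals were 30.5, 85.0 and 73.9 M counts (M, 1000000) for Olfr2- samples 1, 3 and 4, and 363.9, 272.6 and 67.5 M for Olfr2+ samples 2, 3 and 4.

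The columns fell into 2 sets by total count that did not follow the label alone. 7 columns, all labelled Olfr2+ (samples 2A to 2D and 3A to 3C), held 76.0 to 95.6 M counts each. The other 8 held 29.9 to 53.2 M, and comprised the 5 Olfr2- columns and the Olfr2+ columns 3D, 4A and 4B. Pairs of columns within a set had a median correlation of log2 CPM across genes of 0.677, and pairs across sets 0.550; genes are not independent replicates. Columns 3C and 3D, which share a library name, lay in different sets and had a correlation of 0.543. In the deeper set protein-coding genes took 94.6 to 97.46% of the counts, against 78.5 to 80.4% in the other Olfr2+ columns and 79.5 to 85.6% in the Olfr2- columns.

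**Figure D1:**
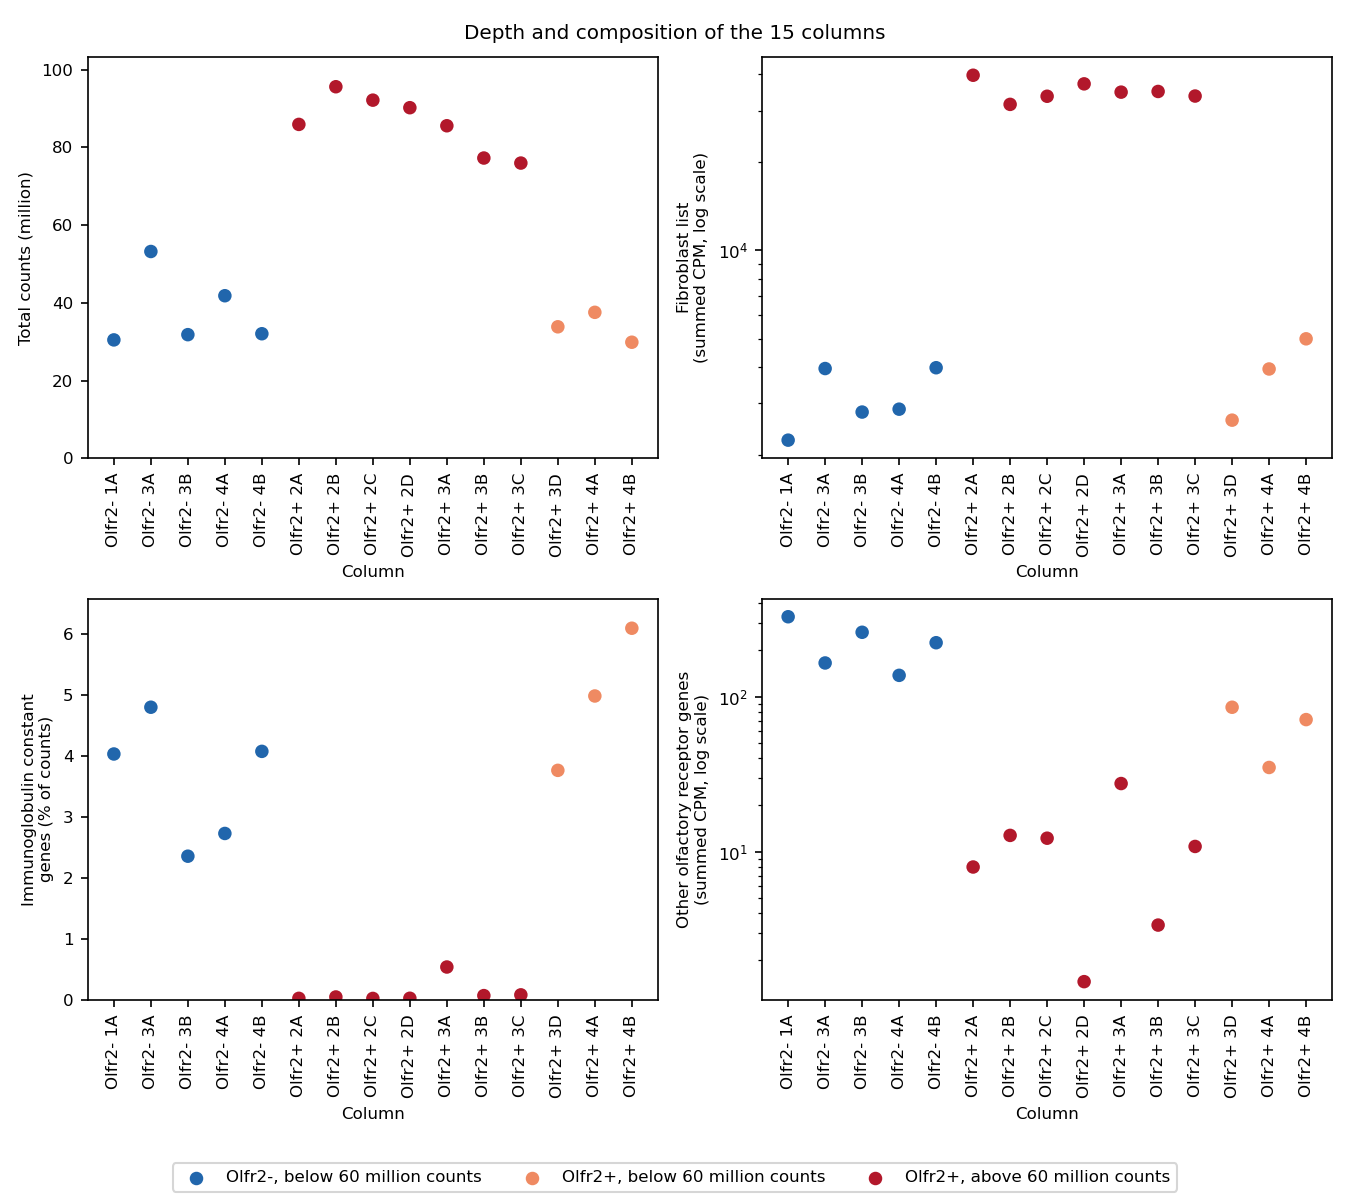
Total counts in M (1000000), summed CPM of the fibroblast list (log scale), share of counts in immunoglobulin constant genes in percent, and summed CPM of the olfactory receptor genes other than Olfr2 (log scale), 1 point per column, coloured by label and by a total above or below 60 M. The 7 deeper Olfr2+ columns sit between 31555 and 39682 CPM for the fibroblast list, and the other 8 columns between 2248 and 4989.

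The Olfr2 transcript went against the label of the sort. It had 76, 34 and 35 counts in Olfr2- samples 1, 3 and 4, and 1, 9 and 8 counts in Olfr2+ samples 2, 3 and 4. The log2 fold change was -3.55 (SE 1.39), with all 3 summed samples labelled Olfr2+ below all 3 labelled Olfr2-, and edgeR's adjusted p was 0.104. By column the labels overlapped, since Olfr2- column 3A had 0 counts and Olfr2+ columns 3D and 4B had 7 each (0.207 and 0.234 CPM). Its log2 fold change was -1.82 (SE 1.13, edgeR adjusted p = 0.561) in the columns below 60 M counts. The 1056 other olfactory receptor genes together were at 175 to 328 CPM in the Olfr2- samples and at 8.69 to 51.0 CPM in the Olfr2+ samples. Directions below are therefore between libraries labelled Olfr2+ and Olfr2-.

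Among the genes called higher over all columns labelled Olfr2+ were 9 of 10 fibroblast list members, 4 of 16 macrophage identity genes and 4 of 18 early response genes. Decorin (Dcn), a collagen-binding proteoglycan, was at 17523 ± 13308 CPM (SD, n = 3) in Olfr2+ and 1027 ± 202 in Olfr2-, a log2 fold change of 4.09 (SE 0.69, edgeR adjusted p = 0.018). Cd74, the invariant chain of MHC class II, was at 16891 ± 12452 against 1638 ± 1102 CPM, a log2 fold change of 3.37 (SE 0.71, edgeR adjusted p = 0.028). In all, 273 genes were higher and 112 lower of 24362 tested, and 7821 had an unadjusted p under 0.05. The 12 with the largest increases were Ccdc107, Zfpl1, Cbr2, Pcyt2, Pltp, Sod3, Mfap4, Fmod, Hspb1, Clec11a, Bmp1 and Creb3l1, with log2 fold changes from 5.96 (Creb3l1) to 6.40 (Ccdc107). Among them Sod3, the extracellular superoxide dismutase, was at 947 ± 864 CPM against 14.04 ± 7.03, Pltp, the phospholipid transfer protein, was at 1190 ± 1204 CPM against 17.6 ± 7.36, and Fmod, a matrix proteoglycan, was at 494 ± 423 CPM against 7.39 ± 3.57 (SD, n = 3 each). In the columns below 60 M counts the log2 fold changes of these 3 were 1.855, 0.63 and 0.40, and those of the 12 ran from 0.40 (Fmod) to 6.93 (Ccdc107). Of the called genes, 208 of the higher and 111 of the lower did not overlap between the groups, as did 35.5% of all genes tested, against 10% by chance.

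Whether genes were called depended on the depth sets and on the settings. With only the columns below 60 M counts, 2 Olfr2+ samples against 3, edgeR called 0 genes, with 3127 at an unadjusted p under 0.05, and a fit with the depth set as a covariate also called 0, with 2610 at an unadjusted p under 0.05. The median log2 fold change of the 273 higher genes went from 5.25 over all columns to 1.4997 in the columns below 60 M counts. Part of this fall may come from choosing these genes with the deeper columns included. For the lower genes the median, in the direction of the call, was 6.64 and 7.0007. The lower genes were chosen for this difference in the same columns, so the second value is no separate check. The deeper set held only Olfr2+ columns, so it gave no comparison of its own. Camera called 13 lists higher in the columns below 60 M counts, 9 of them among the 11 called over all columns. With an estimated correlation camera called 0 there (smallest adjusted p 0.343). The median log2 fold change of all genes tested there was -0.43, and camera sets a list against the other genes. The summed CPM of each of the 13 lists overlapped between the labels in those columns. Oxidative phosphorylation genes, for example, took 2948 to 3237 CPM in Olfr2+ and 1226 to 4321 in Olfr2-. With a mean of at least 10 CPM required, edgeR called 0 of 8504 genes (1389 at an unadjusted p under 0.05). That setting also recomputed the TMM factors, from 1.337 to 1.66 in Olfr2- and 0.485 to 0.868 in Olfr2+ to 0.666 to 1.02 and 0.996 to 1.31, and took Dcn to 2.30. With the planned scaling kept, the same 8504 genes gave 526 higher and 3 lower, and the planned filter with the recomputed scaling gave 90 and 705. Over those 8504 genes camera called only the fibroblast list higher, under either scaling. With their usual filters limma-voom called 0 of 24362 (7537 at an unadjusted p under 0.05), and DESeq2 called 4017 higher and 2690 lower of 28701. Scaling by library totals alone moved the median log2 fold change of all genes by -1.12 and gave 86 higher and 310 lower genes. Leaving out Olfr2- sample 1, 3 or 4 gave 100, 68 and 90 higher and 12, 13 and 30 lower genes, and leaving out Olfr2+ sample 2, 3 or 4 gave 6, 102 and 973 higher and 0, 3 and 113 lower.

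**Figure D2:**
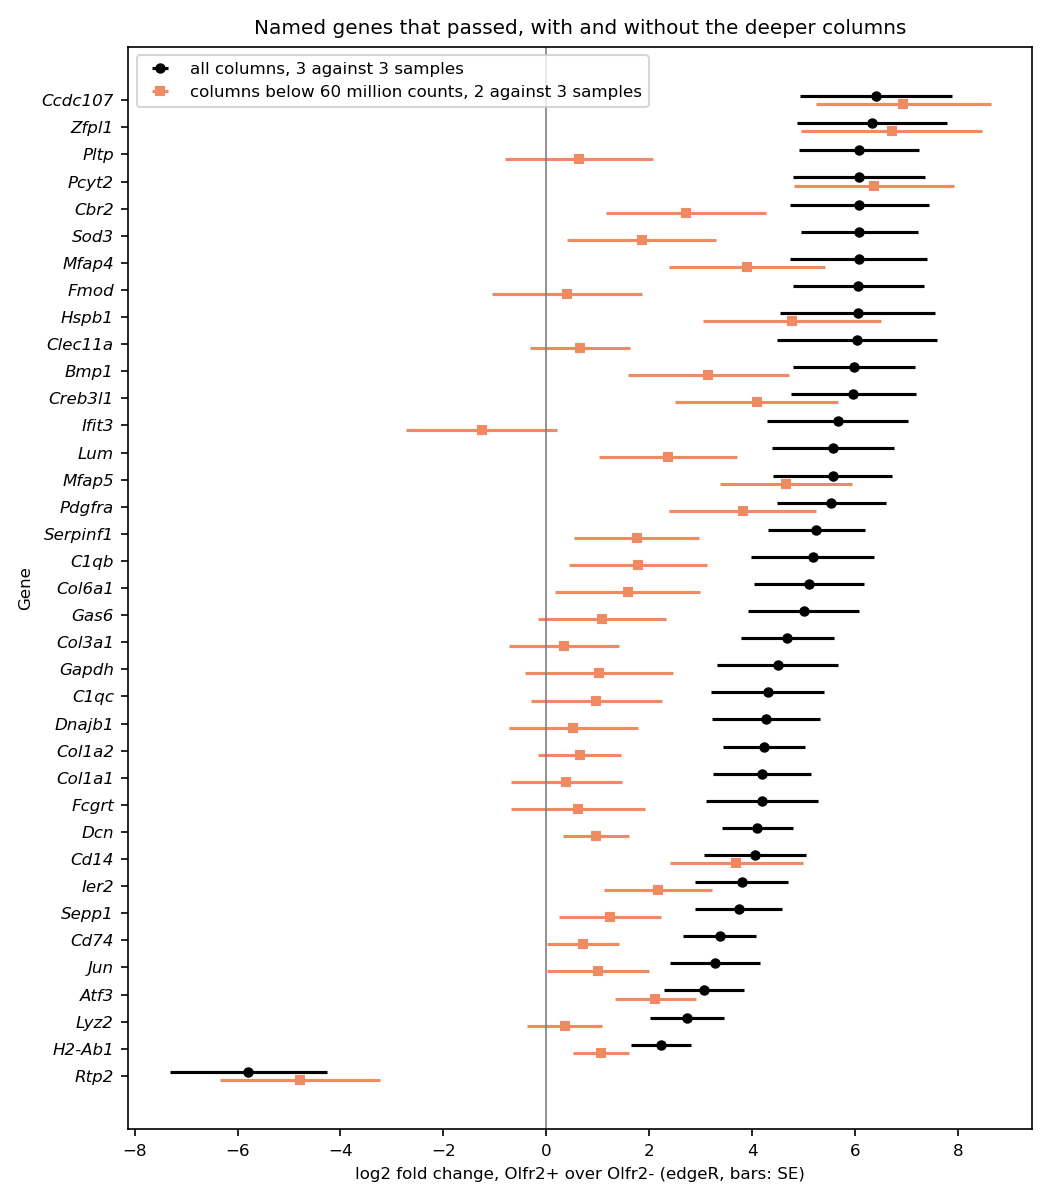
Log2 fold change of Olfr2+ over Olfr2- with its standard error for each named gene that passed, from all columns (black circles, 3 against 3 samples) and from the columns below 60 M counts (orange squares, 2 against 3 samples). Dcn moved from 4.09 to 0.97 and Ifit3 from 5.66 to -1.26, and Ccdc107 stood at 6.40 and 6.93.

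Fibroblast genes rose most. 9 of the 10 list members rose, 0 fell and 1 did not pass, and 10 rose when adjusted over the list alone (camera adjusted p = 8.76e-06, median log2 fold change 4.89). The call was lost with the correlation estimated (adjusted p = 0.363 with an estimated correlation). Col1a2, a chain of type I collagen, was at 8640 ± 8097 CPM against 461 ± 187, Col3a1, of type III collagen, at 5130 ± 5007 against 200.2 ± 113, and Pdgfra, a receptor typical of fibroblasts, at 539 ± 224 against 11.6 ± 3.07 (SD, n = 3 each). Within the columns below 60 M counts the log2 fold changes were 0.65 (SE 0.81) for Col1a2, 0.34 (SE 1.07) for Col3a1 and 3.82 (SE 1.43) for Pdgfra, and edgeR's adjusted p was 0.789, 0.925 and 0.435. The list's median there was 1.27 (camera adjusted p = 0.0025, and 0.432 with an estimated correlation), and its sums overlapped, at 2631 to 4989 CPM in Olfr2+ and 2248 to 3974 in Olfr2-.

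A minority of macrophage genes were called higher as well. Of the 16 macrophage identity genes 4 rose, 0 fell and 12 did not pass, and 5 rose when adjusted over the list alone (camera adjusted p = 0.0022). The 4 were the complement genes C1qb and C1qc, lysozyme (Lyz2) and the endotoxin co-receptor Cd14, with log2 fold changes of 5.18, 4.30, 2.73 and 4.05, and of 1.77, 0.97, 0.35 and 3.69 in the columns below 60 M counts; all but Cd14 overlapped between the labels. The 17 genes of resident-like arterial macrophages had 4 that rose and 13 that did not pass, and 7 rose when adjusted over the list alone (camera adjusted p = 3.50e-04). Those 4 were Cbr2, Fcgrt, the TAM receptor ligand Gas6 and the selenium carrier Sepp1, with log2 fold changes of 6.08, 4.18, 4.996 and 3.74, and of 2.705, 0.61, 1.079 and 1.23 in the columns below 60 M counts; Fcgrt overlapped between the labels. Both calls were lost with the correlation estimated (adjusted p = 0.363 with an estimated correlation in each). In the columns below 60 M counts the medians were 0.81 and 0.45, with camera adjusted p of 0.011 and 0.084 (0.343 and 0.432 with an estimated correlation).

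The genes of antigen presentation by MHC class II, of the interferon response and of immediate early and dissociation stress were called by camera with adjusted p of 0.0024, 1.78e-04 and 7.04e-04. Of 13 MHC class II genes, Cd74 and H2-Ab1 rose and 11 did not pass, and 6 rose when adjusted over the list alone. Of 20 interferon genes only Ifit3 rose and 19 did not pass, and 7 rose when adjusted over the list alone; its log2 fold change was 5.66 (SE 1.36) overall and -1.26 (SE 1.47) in the columns below 60 M counts. Of 18 early response genes Atf3, Dnajb1, Ier2 and Jun rose and 14 did not pass, and 8 rose when adjusted over the list alone. The 3 lists were also called higher in the columns below 60 M counts, with medians of 1.15, 0.75 and 1.06 and camera adjusted p of 0.0023, 0.0045 and 1.36e-04 (0.432, 0.343 and 0.343 with an estimated correlation). The 3 calls were lost with the correlation estimated (adjusted p = 0.363 with an estimated correlation in each).

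Metabolic lists were called higher while few or no members passed. Glycolysis had 1 of 16 genes that rose, Gapdh, with a log2 fold change of 4.49 (SE 1.18) over all columns and 1.03 (SE 1.44, edgeR adjusted p = 0.815) in those below 60 M counts, and 15 that did not pass, and 11 rose when adjusted over the list alone (camera adjusted p = 1.21e-04). Oxidative phosphorylation had 0 of 27 that passed, with 2 higher when adjusted over the list alone (camera adjusted p = 2.51e-05). The foamy macrophage and lipid handling list had 0 of 21 that passed, with 8 higher when adjusted over the list alone (camera adjusted p = 0.0030). Its most abundant members, cathepsin B (Ctsb), lipoprotein lipase (Lpl) and galectin 3 (Lgals3), had log2 fold changes of 2.25 (SE 0.71), 2.54 (SE 0.83) and 1.89 (SE 0.78). Glycolysis and oxidative phosphorylation were also called in the columns below 60 M counts (camera adjusted p = 0.0013 and 1.99e-04, medians 1.05 and 0.94, and 0.432 each with an estimated correlation), and the foamy macrophage list was not (0.195, median 0.47 against 1.96 over all columns). The median of the foamy macrophage list also depended on the scaling. On library totals it was 0.86 over all columns, where camera still called the list (adjusted p = 0.0099). The 3 calls over all columns too were lost with the correlation estimated (adjusted p = 0.363 with an estimated correlation in each).

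The monocyte list (camera adjusted p = 0.025) and the cytosolic ribosomal protein list (0.026) were the remaining calls, with 0 of 15 and 0 of 29 members past the test and 1 and 0 when adjusted over the list alone. Their adjusted p was 0.363 and 0.452 with an estimated correlation, and 7.59e-05 and 4.85e-05 in the columns below 60 M counts (0.343 and 0.432 there with an estimated correlation). With at least 10 CPM required and the scaling recomputed both turned, to a camera adjusted p of 0.305 and 0.025 in the lower direction. With the planned scaling kept they turned as well (0.786 and 0.175) while their medians were 1.32 and 0.69, since camera sets a list against the other genes tested. Neither was called on library totals (camera adjusted p = 0.120 and 0.137, with the ribosomal median at -0.38) or with the planned filter under the recomputed scaling (0.165 and 0.182). The summed CPM of the ribosomal list went against its call in the deeper Olfr2+ columns, at 6451 to 9487. It was 18772 to 20120 in the other Olfr2+ columns and 15273 to 20598 in the Olfr2- columns. Over genes of at least 10 CPM with the scaling recomputed, the fibroblast list was the only one called higher, and the cell cycle, dendritic cell, T and NK cell, B cell and ribosomal lists were called lower, with camera adjusted p of 0.025, 0.027, 0.0059, 0.044 and 0.025; with the planned scaling kept the first 4 of these were called lower (0.0059, 0.018, 4.96e-04 and 0.0024).

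Over all columns the inflammatory list and the cytokines that the study names were not called, with camera adjusted p of 0.058 over 22 genes and 0.349 over 10, and 0 members of either passed, also when adjusted over the list alone. The inflammatory list was called higher in the columns below 60 M counts (camera adjusted p = 0.0046, median 1.07; 0.343 with an estimated correlation), and the second was not (0.468, median -0.49). The second list was taken from the study's own description and is not independent evidence. Interleukin 1 beta (Il1b) was at 971 ± 563 CPM in Olfr2+ and 631 ± 183 in Olfr2-, interleukin 6 (Il6) at 224 ± 180 against 26.5 ± 28.8, tumour necrosis factor (Tnf) at 129 ± 27.2 against 27.2 ± 12.1 and Ccl5 at 45.0 ± 32.4 against 86.4 ± 111 (SD, n = 3 each). Their log2 fold changes were 0.62 (SE 0.76), 3.08 (SE 1.14), 2.24 (SE 1.10) and -0.94 (SE 1.27), and edgeR's adjusted p was 0.547, 0.094, 0.158 and 0.585. On library totals the list medians of 1.09 and 0.71 became -0.06 and -0.40. Cell cycle genes, with 0 of 22 past the test, had a camera adjusted p of 0.474 and a median of -0.09 although camera pointed upwards; Top2a was at 61.1 ± 69.6 CPM against 111 ± 80.6.

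Over all columns the other cell type, cholesterol and mitochondrial lists were not called by camera. Fry called 1 of them, the adipocyte and mesothelial list, lower (fry adjusted p = 0.037). None of the members of the neutrophil (8 tested), endothelial (10), smooth muscle (10), dendritic cell (11), T and NK cell (14), B cell (9), adipocyte and mesothelial (9) and erythroid and platelet (6) lists passed over all genes, nor did any of the 19 genes of cholesterol synthesis or the 13 mitochondrially encoded genes. Adjusted over the list alone, 1 neutrophil, 3 smooth muscle and 2 mitochondrial genes were higher, and 1 smooth muscle and 2 erythroid genes were lower. The camera adjusted p values were 0.073, 0.474, 0.598, 0.560, 0.469, 0.994, 0.075 and 0.349 for the cell types in that order, 0.080 for cholesterol synthesis and 0.146 for mitochondrial genes. The endothelial median of 0.56 and the dendritic cell median of -0.29 had the opposite sign to the test. Called higher in the columns below 60 M counts were the B cell (camera adjusted p = 0.0013, median 1.39), neutrophil (0.0089, 0.53) and mitochondrial (4.98e-04, 1.083) lists, with an adjusted p of 0.343 each with an estimated correlation. The summed CPM of the mitochondrial list went against its call in these columns, with medians of 8596 in Olfr2+ and 13003 in Olfr2-. Its ranges overlapped, at 8505 to 11732 and 5100 to 13725. For B cells over all columns fry pointed down while camera and the median of 1.41 pointed up. The B cell list took 107 to 4572 CPM in the deeper columns, 12251 to 22202 in the other Olfr2+ columns and 5044 to 17757 in the Olfr2- columns.

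The 112 lower genes were nearly all close to the detection floor. For 111 of them the mean over the samples was under 1 CPM, and the exception was an antisense gene model with overlapping groups. Their median log2 fold change was -6.64. The odorant receptor signalling list was not called (camera adjusted p = 0.126), with 1 of 12 members that fell, Rtp2, a chaperone of odorant receptors, and 11 that did not pass; 1 fell when adjusted over the list alone. Rtp2 was at 0.0128 ± 0.0116 CPM in Olfr2+ and 0.869 ± 0.968 in Olfr2- (SD, n = 3 each).

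**Figure D3:**
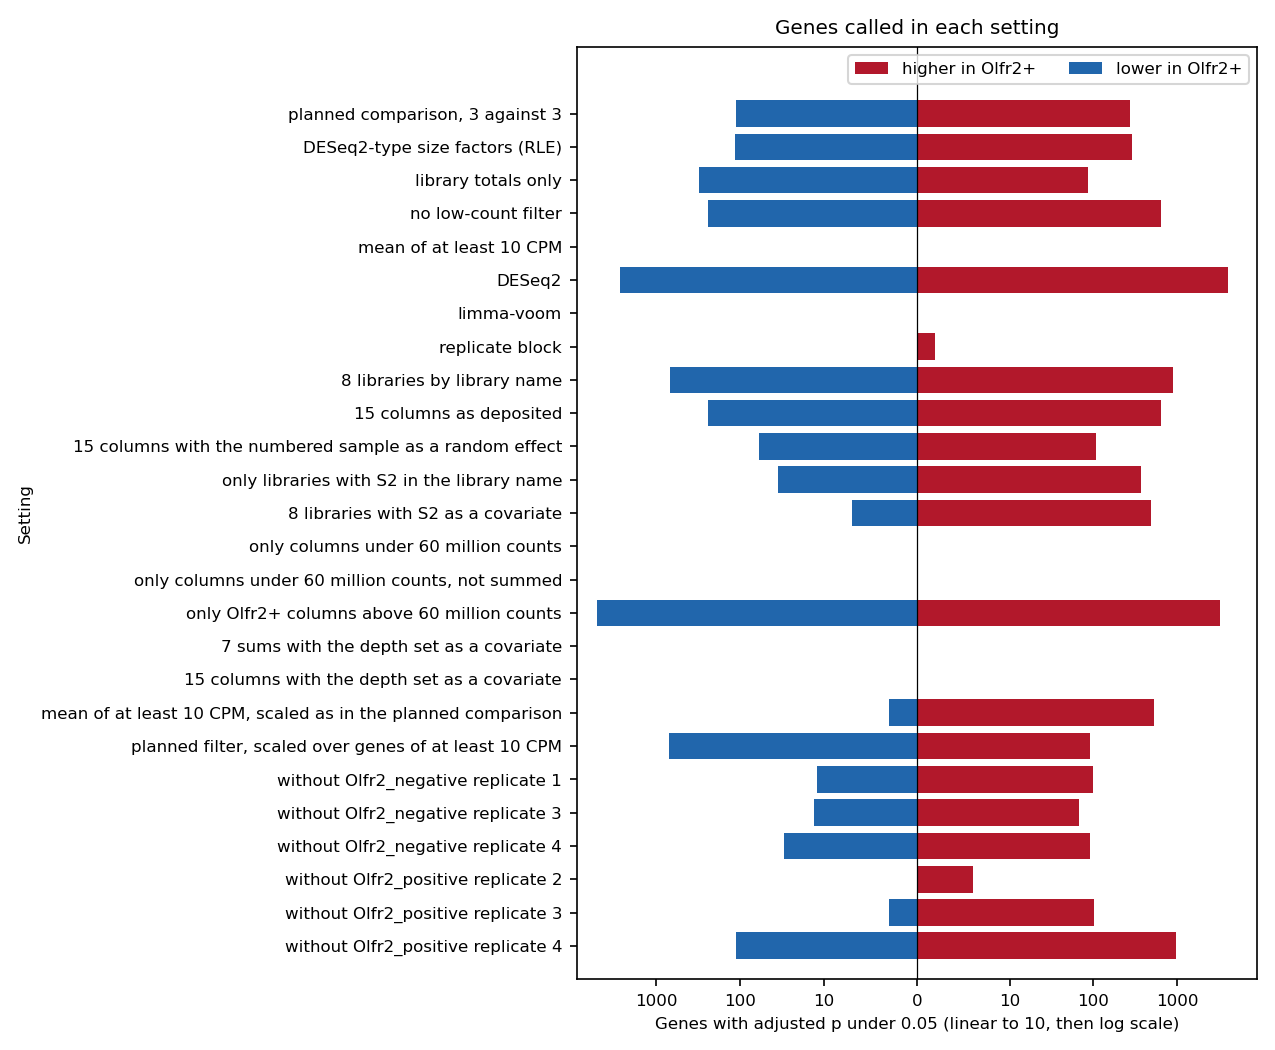
Genes called higher (right, red) and lower (left, blue) in Olfr2+ at an adjusted p under 0.05 in the planned comparison and in each alternative, on an axis that is linear to 10 and logarithmic beyond. The planned comparison has 273 and 112, and the settings that keep or adjust for the columns below 60 M counts have 0.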

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

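The tests of the depth sets, of library size, of fibroblast RNA and of a lower share of macrophage RNA were chosen after the result was seen, and those of gene length, of background reads and of other splits before; that of library size was first written before for all called genes together and was divided by direction after. Among 64 checks of columns within a label, 5 had 1 column far from the rest, and 3.2 are expected by chance. Column 2A of Olfr2+ had 206.9 CPM of odorant receptor signalling genes against 98.2 in the next, of which Ric8b gave 159. Column 4B of Olfr2+ had 3397 CPM of dendritic cell genes against 1543, led by Ccr7 at 1751. Column 3B of Olfr2+ had 770.0 CPM of endothelial genes against 108, led by Pecam1 at 690.0. Column 1A of Olfr2- had 375 CPM of erythroid and platelet genes against 7.89, led by Hbb-bs at 294, and column 3C of Olfr2+ had 26.4 CPM against 8.02, led by Gp1bb at 25.04.

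The first pattern weighed is the 385 called genes, for which a difference between Olfr2+ and Olfr2- cells stays open, for the higher genes as part of the change. For the 273 higher genes the median log2 fold change was 5.25, and between deeper and other columns of the same Olfr2+ label it was 4.05 (quartiles 2.87 and 5.41) against 1.4997 (0.57 and 2.77) between the labels in the columns below 60 M counts, as a library batch that follows the totals would give. These genes were chosen from sums in which Olfr2+ samples 2 and 3 are mostly the deeper columns. Part of the contrast between the 2 values may therefore come from that choice. Thinning each sample to 30.5 M counts left these higher genes at a median of 4.38 (quartiles 4.03 and 4.75). It ended the calls, at a smallest edgeR adjusted p of 0.052 and with a median SE of 1.15 after against 1.22 before. Thinning keeps each gene's expected share of the counts, so by itself it could hardly lower fold changes at their median level of 112 CPM. The refit also filtered and scaled the genes anew, over 18970 of them instead of 24362. The source of the fall from 5.25 to 4.38 was not tested. Thinning therefore does not decide on library size. An average trend over gene length accounted for little of the size of the changes. With that trend removed the median over all 385 genes was 5.44, from 5.59. For the 112 lower genes neither batch nor library size can be told apart from the label, because 1 of them could be tested within Olfr2+ and 25 after thinning (median 6.80 in the direction of the call), and their median of 7.0007 between the labels in the columns below 60 M counts comes from genes chosen for this difference in the same columns, so it decides nothing; the rule that 80% be tested, which set aside that value for the batch, was added after it was seen. The 10 splits of the 6 samples are too few for a share under 0.05: the real one gave 273 higher and 112 lower genes, as many as which were reached by 1 and 3 splits, with 233 the highest other count in 1 direction, in a split that sets Olfr2+ samples 2 and 3, which hold the deeper columns, and Olfr2- sample 3 against the rest, and 11 called lists were reached by 2 splits, with 13 the highest other.

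The second pattern is the fibroblast genes, which a sort on F4/80 and CD64 would be meant to exclude. Of 12 fibroblast transcripts outside the list, 10 were higher in each of the 7 deeper columns than in each other column, against a median of 1 and at most 6 in 2000 draws of genes of like abundance, and the most abundant, Gsn, had a median of 18443 CPM there against 863, so RNA from fibroblasts in those libraries is a candidate explanation. The 12 were chosen after the list was seen to part the same columns. The draws took genes singly, so they are no reference for genes that vary together. A lower share of macrophage RNA as the cause would raise other cell types too. An equal rise is argued against for 2 of 3 lists, since the endothelial and B cell lists had upper quartiles of 1.55 and 2.74 against a lower quartile of 4.20 for the fibroblast list. The smooth muscle list reached 4.37. The medians of the endothelial, B cell and smooth muscle lists (0.56, 1.41 and 2.85) were above 0, which was the outcome set for this cause. Those medians depended on the scaling, and on library totals they were -0.74, 0.58 and 1.54. The macrophage identity list was not lower over all columns. All 16 estimates were above 0, with a median of 2.37, and of 1.01 on library totals. Its sum was 9358 to 17318 CPM in the deeper columns, 5394 to 8020 in the other Olfr2+ columns and 4425 to 11285 in Olfr2-. For these genes the values argue against a lower share of macrophage RNA. Whether fibroblast RNA entered with the sorted cells or with the handling of the deeper set stays open. So does transcription of the fibroblast genes in the sorted macrophages. The sort label as given cannot account for the whole pattern. The list took 31555 to 39682 CPM in the deeper Olfr2+ columns and 2631 to 4989 in the other Olfr2+ columns. In Olfr2- it took 2248 to 3974. If the labels are right, a smaller part from a difference between the sorted cells stays open. Whether columns 3D, 4A and 4B are rightly labelled was not tested.

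The third pattern is that Olfr2 counts were higher in libraries labelled Olfr2-. Per kilobase of exon, Olfr2 lay at the 87.4th percentile of the 1056 other olfactory receptor genes in the Olfr2- samples, at 0.167 CPM per kilobase against their median of 0.048, so its counts may be part of a background over silent genes. Counts over those other genes together were at 137 to 328 CPM in the Olfr2- columns, 35.0 to 85.6 in the Olfr2+ columns below 60 M counts and 1.45 to 27.5 in the deeper ones. A mislabelled sort and a lower transcript level in the sorted cells stay open, as untested.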

How the results depend on the processing

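The comparisons by depth set, the list tests on library totals and the 2 settings that part the 10 CPM filter from its scaling were chosen after seeing the data. DESeq2-type size factors gave 291 higher and 116 lower genes. The counts of higher and lower genes were 86 and 310 on library totals, 642 and 239 without a low-count filter, 0 and 0 at a mean of at least 10 CPM with its own scaling, 526 and 3 there with the planned scaling, 90 and 705 with the planned filter and the scaling of the 10 CPM genes, 4017 and 2690 with DESeq2, 0 and 0 with limma-voom, 885 and 683 over 8 libraries, 649 and 244 over 15 columns, 106 and 60 with the numbered sample as a random effect, 372 and 35 with the libraries whose name holds S2, and 486 and 7 with S2 as a covariate. They were 0 and 0 with the columns below 60 M counts (edgeR, 3127 at an unadjusted p under 0.05), also when not summed (2900), with the depth set as a covariate over 7 sums (2610) and over 15 columns (1432), and 3228 and 5129 with the deeper Olfr2+ columns alone. Leaving out 1 sample gave 6 to 973 higher and 0 to 113 lower genes. All Olfr2- libraries hold S2 in their name, and Olfr2+ sample 4 has no such library. The setting with only S2 libraries thus left out that sample, and its Olfr2+ columns were deeper ones except 3D. S2 varied only among the Olfr2+ libraries. Neither S2 setting parts the label from the depth set. With the sample number as a replicate block 2 and 0 genes were called; samples 3 and 4 share only a number, and deviations of same-numbered samples had correlations of -0.015 and -0.052. The cause was not tested for these changes, except at 10 CPM, where the calls ended only with filter and scaling changed together. The Olfr2 gene kept its negative sign in every setting that tested it (its level is under 10 CPM), was nearer 0 with the columns below 60 M counts (-1.82 summed, -1.55 not summed), the depth set as a covariate (-1.98 and -1.88), the block (-1.92) or without Olfr2- sample 1 (-2.40), and passed with DESeq2 (-3.40) and with the deeper columns alone (-6.08). Of the 37 other named genes that passed, 34 also passed with DESeq2-type factors, 21 on library totals and 0 with the columns below 60 M counts. Ifit3 changed sign there (-1.26), also when not summed (-1.63) and with the depth set as a covariate (-1.32 and -1.82), and over 15 columns with that covariate Col1a1 (-0.066), Fcgrt (-0.049) and Lyz2 (-0.16) did. Camera called 11 lists, 0 with an estimated correlation, 6 at 10 CPM (5 with the planned scaling), 13 with the columns below 60 M counts (0 with an estimated correlation) and 12 to 15 without 1 sample, and fry called 2. Those 2 were the immediate early and dissociation stress list, higher, and the adipocyte and mesothelial list, lower (fry adjusted p = 0.037 each). At 10 CPM, with its own and with the planned scaling, the direction turned for the monocyte (adjusted p = 0.305 and 0.786), cell cycle (0.025 and 0.0059), ribosomal (0.025 and 0.175), dendritic cell (0.027 and 0.018) and B cell (0.044 and 0.0024) lists. Sign changes of lists and genes past the threshold in neither setting are not counted. In the comparison of the columns below 60 M counts simulated changes of 5 on the log2 scale were recovered in 4 of 50 genes, against 20 of 50 in the main one.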

Other observations

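The columns below 60 M counts, whatever their label, held more immunoglobulin and mitochondrial ribosomal RNA than the deeper ones. Constant genes of immunoglobulins took 2.35 to 4.80% of the counts in the Olfr2- columns and 3.76 to 6.09% in the Olfr2+ columns below 60 M, against 0.024 to 0.539% in the deeper columns. The mitochondrial 16S ribosomal RNA gene mt-Rnr2 took 4.77 to 8.25%, 5.48 to 9.14% and 0.663 to 3.03% in the same order. Cytosolic ribosomal protein genes were at 15273 to 20598, 18772 to 20120 and 6451 to 9487 CPM.

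A few genes had large log2 fold changes between the labels in the columns below 60 M counts. There Ccdc107 stood at 6.93 (SE 1.70), Zfpl1 at 6.71 (SE 1.75), Pcyt2, of phosphatidylethanolamine synthesis, at 6.37 (SE 1.56) and Cd14 at 3.69 (SE 1.29), with edgeR adjusted p of 0.411, 0.411, 0.411 and 0.423. Over all columns the first 3 were highest in Olfr2+ sample 4. There Ccdc107 was at 358 TMM-scaled CPM against 26.4 and 28.9 in Olfr2+ samples 2 and 3, and Zfpl1 at 328 against 62.7 and 31.6. Cd14 was also highest in that sample. Without sample 4 the first 3 stood at 4.12, 4.78 and 4.77 over all columns, against 6.40, 6.33 and 6.08 with it. Cd14 stood at 3.57 against 4.05. That sample thus enlarged the differences over all columns. Without it Ccdc107 and Zfpl1 did not pass (edgeR adjusted p = 0.060 and 0.055), and Pcyt2 did (0.049). The Olfr2+ side was then samples 2 and 3, all deeper columns except 3D. What remained therefore cannot be told apart from a difference between the depth sets. These genes were singled out after their values were seen.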
